A study of Homo sapiens with 12 samples.

How the data were processed

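The data are RNA-seq libraries of KHM-5M and TTA-1 cells treated with 1 µM GDC-0994 or DMSO for 24 hours, 12 libraries in 4 groups of 3. Per the labels, mRNA was selected on poly-T beads, converted to cDNA from random hexamers, ligated to hairpin adaptors and amplified by PCR, with no step that marks the strand. The labels name CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3 and the GRCh38 build, without stating the role or order of each. The deposited table of counts holds raw counts per gene and library, which were whole numbers with a different total in each library. The deposited table of FPKM holds fragments per kilobase of gene length, which the authors scaled by a library size per sample. Tested on the values, each FPKM equalled the count divided by the gene length and by 1 library size, within a relative error of 4.99e-08, at 0.975 to 1.08 times the library's total count, with 0 genes at 0 in one table and above 0 in the other. All 58735 gene IDs were found in GENCODE 29 with the same start, end and exon length. As deposited, 27 symbols appear as dates, and these genes were named through their IDs. No count was above 0 in any library for 26222 genes.

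Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 4 groups (minimum count 10, minimum total 15), scaled by TMM, and fitted with quasi-likelihood models (glmQLFit and glmQLFTest) in 1 model of all 12 libraries with a mean per group and 8 residual degrees of freedom. The comparisons were GDC-0994 over DMSO in each line, the difference of these effects (KHM-5M minus TTA-1), and KHM-5M DMSO over TTA-1 DMSO. The p-values were adjusted by the Benjamini-Hochberg method over the 16218 genes tested, and a gene was called, or said to have risen or fallen, at an adjusted p below 0.05. Standard errors of log2 fold changes were derived from the fold change and the F statistic. Overlap between lines was tested with Fisher's exact test, one-sided, and the MAPK output score, the mean log2(CPM + 1) of 10 genes per library, with an exact permutation test. The replicate numbers were not taken to pair libraries, as fixed beforehand. In a check on the data, correlations across genes of library ratios ranged from -0.146 to 0.272 for the same number. For different numbers they ranged from -0.410 to 0.411. The labels repeat 1 column name for the 3 KHM-5M GDC-0994 samples, whose replicate numbers were matched to the numbers in the column names, and the replicate block in KHM-5M depends on this.

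Gene lists were tested with camera (preset correlation 0.01), with camera with an estimated correlation, and with fry, in limma 3.58.1, adjusted over the 31 lists of a comparison that had at least 3 tested members. The lists were MAPK output, RAS-RAF-MEK-ERK members, immediate-early and AP-1 genes, other ERK negative feedback genes, DNA replication and E2F, mitosis, cell cycle arrest and quiescence, BCL2 family, p53 targets, thyroid differentiation, glycolysis, nuclear oxidative phosphorylation, ribosome biogenesis and MYC targets, serine, one-carbon and ATF4 targets, cholesterol synthesis, fatty acid synthesis, lysosome and autophagy, interferon response, antigen presentation, cytokines and NF-kB targets, mesenchymal and matrix genes, epithelial genes, YAP and TEAD targets, receptor tyrosine kinases and ligands, NRF2 targets and ferroptosis genes, replication-dependent histones, mitochondrially encoded genes, and markers of blood, endothelial, melanocytic and neural, and C cells. Pairs of lists share at most 3 genes. The fry test, which asks whether a list's genes move one way on balance, called 25 lists in KHM-5M, 9 in TTA-1, 18 for the difference and 28 in DMSO.

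The comparisons, tests, lists, rule for named genes and most alternatives were fixed before the data were examined. The rule takes, for each treatment comparison, the 10 protein-coding genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 1 CPM in both groups and no overlap between treated and control libraries. It takes 8 in each direction for the difference, with at least 1 CPM in all groups, and 10 in each direction for the DMSO comparison, with at least 20 CPM in the higher line. It adds all members of the MAPK output and RAS-RAF-MEK-ERK lists, and up to 2 risen and 2 fallen members of every other list by smallest p. X inactivation transcripts, Y-linked genes and near-identical HLA genes were left out, and some genes that the rule takes are not reported here.

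Alternatives fixed beforehand were DESeq2 1.42.0 size factors and Wald test, no filter, a stricter filter (at least 1 CPM in 3 libraries and a mean count of 50), a model of only the groups compared, a replicate block, limma on log2(FPKM + 1) with and without a filter at an FPKM of 1, limma on log2(FPKM + 0.1) with that filter, a minimum log2 fold change of 1, and leaving out each library in turn. Chosen after seeing the data were thinning all libraries to the smallest total, upper quartile scaling, scaling by library totals, and removal of a trend on gene length and GC content from each library.

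Total counts per library ranged from 14952970 to 18389915. Fold changes against a group with 0 counts were bounded with a floor of 3 counts per library, and intervals for groups with 1 to 3 counts are 95% intervals. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. The pipeline was tested on simulated data with 100 genes changed at each fold in each line. At a fold of 2 it recovered 90% of them in KHM-5M and 89% in TTA-1, and at a fold of 1.5 it recovered 57% and 66%. Of its calls 5.16% and 6.06% were false. Without simulated changes it called 1 gene in KHM-5M, 0 in TTA-1 and 2 for the difference among 15941 genes, and 0 of 31 lists. In TTA-1 that is 0 in edgeR, with 4.66% of genes at an unadjusted p under 0.05. The simulated counts were drawn gene by gene from the fitted spread, equal in both lines, without trends of whole libraries or links between genes. These rates hold for such data and do not give the rate of false calls in the real libraries. Reads of overlapping genes were not told apart, since no strand was recorded. At least 20% of the exon bases overlapped another gene for BCL2L1 (42.97% with ABALON), DUSP6 (40.5%) and TAP2 (32.3%) with genes that have a clone name alone, PLAU (31.1% with C10orf55), TGFB2 (26.6% with TGFB2-OT1), RAD54L (25.1% with LRRC41), MT-ATP8 (22.2% with MT-ATP6) and SQSTM1 (20.7% with MRNIP). Smaller overlaps included 10.9% for BCL2L11 with MIR4435-2HG, 10.3% for CCND1 with LTO1 9.26% for PAX8 with PAX8-AS1 and 9.23% for ELF3 with ELF3-AS1. MT-ATP6 lies on the same strand as MT-ATP8 and had a mean count of 42716 against 220.5. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.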

Results

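Polyadenylated RNA was sequenced from 2 human anaplastic thyroid carcinoma cell lines, derived from the undifferentiated form of thyroid cancer. KHM-5M was labelled as carrying BRAF V600E, a change that keeps the kinase BRAF active, and grew in RPMI-1640. TTA-1 was labelled BRAF wild type and grew in DMEM. Each line received 1 µM GDC-0994 (ravoxertinib), an inhibitor of the ERK kinases at the end of the RAS-RAF-MEK-ERK cascade, or its vehicle DMSO for 24 hours, with 3 libraries per group and 4 groups. The total counts were 17397430, 16892674 and 16997408 in KHM-5M DMSO replicates 1, 2 and 3, and 18389915, 16917342 and 15218155 in KHM-5M GDC-0994 replicates 1, 2 and 3. They were 16035103, 15996718 and 16518063 in TTA-1 DMSO, and 15652517, 15562553 and 14952970 in TTA-1 GDC-0994, in the same order. Of 58735 annotated genes, 16218 passed the filter on low counts and were tested, 13260 of them protein coding. Values after ± are the standard error of a log2 fold change, or the SD over the 3 libraries (n = 3) of a level in CPM (the count scaled to library size), a percentage or a score, and positions are on GRCh38.

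The lines separated on the first principal component of log2 CPM (86.0% of the variance), and the second (9.38%) separated the treatment groups, from 41.3 to 44.1 in DMSO and -41.8 to -37.4 in GDC-0994 in KHM-5M, and from 0.088 to 6.55 and -7.45 to -5.6036 in TTA-1. Mitochondrially encoded genes took 3.09 ± 0.215% of the counts in KHM-5M DMSO, 4.04 ± 0.239% in KHM-5M GDC-0994, 4.33 ± 0.183% in TTA-1 DMSO and 4.49 ± 0.425% in TTA-1 GDC-0994. TTA-1 DMSO replicates 1 and 2 lay farthest apart of all replicate pairs, with a mean absolute log2 difference of 0.288 against 0.141 to 0.222 in the other pairs. Across 9527 genes, which are not independent replicates, the log2 ratio of a TTA-1 DMSO library to the other TTA-1 DMSO libraries had a correlation with GC content of 0.74 in replicate 1, -0.70 in replicate 2 and 0.16 in replicate 3.

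The comparison of GDC-0994 with DMSO in KHM-5M asked which genes respond to ERK inhibition in a line with BRAF V600E. Transcripts that report ERK activity fell. In the MAPK output list, 9 of 10 members fell and 1 rose (9 and 1 adjusted over the list alone), with a median log2 fold change of -2.80 (adjusted p = 9.49e-34). ETV4 (ENSG00000175832, chromosome 17, 43527844 to 43579620), an ETS transcription factor, fell from 127 ± 3.15 to 3.42 ± 0.545 CPM, a log2 fold change of -5.20 ± 0.14 (adjusted p = 7.46e-14). DUSP6 (ENSG00000139318, chromosome 12, 89347232 to 89353271), a phosphatase that acts on ERK, fell from 33.1 ± 2.91 to 1.89 ± 0.471 CPM (-4.11 ± 0.25 log2). CCND1 (ENSG00000110092, chromosome 11, 69641087 to 69654474), which encodes cyclin D1, fell from 529.6 ± 18.6 to 79.4 ± 5.03 CPM (-2.74 ± 0.08 log2). The log2 fold changes of the other members that fell were -3.86 for ETV5, -3.12 for SPRY4, -2.86 for SPRY2, -2.64 for DUSP4, -2.63 for PHLDA1 and -1.55 for EPHA2. EPHA4, an ephrin receptor, rose from 0.114 ± 0.0970 to 1.12 ± 0.311 CPM (3.20 ± 0.70 log2, and 4.13 without KHM-5M DMSO replicate 1). The mean log2(CPM + 1) over the list was 5.80 ± 0.03 in DMSO and 3.23 ± 0.06 in GDC-0994, a difference of -2.58 (exact permutation test of both sides, p = 0.1, the smallest that 3 against 3 libraries allow).

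**Figure D1:**
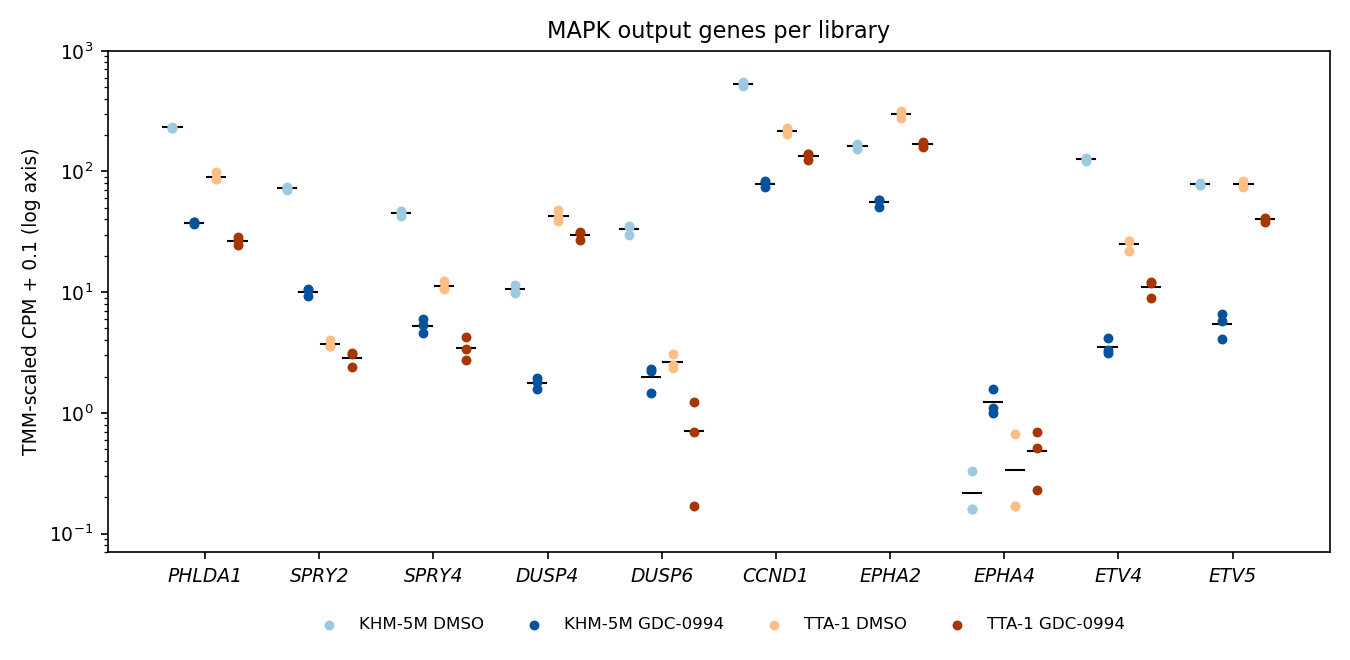
TMM-scaled CPM plus 0.1 on a log axis for the 10 MAPK output genes, 1 point per library, with a bar at the mean of the 3 libraries of each group. In KHM-5M all members except EPHA4 lie lower with GDC-0994, and ETV4 fell from 127 to 3.42 CPM there against 24.9 to 10.9 CPM in TTA-1.

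Other ERK-responsive genes fell in KHM-5M as well. Of 24 immediate-early and AP-1 genes, 15 fell, 5 rose and 4 were not called, with the same counts adjusted over the list alone. Most of these genes encode transcription factors that respond quickly to growth signals. The list had a median of -0.63 (list test, adjusted p = 7.99e-04, and adjusted p = 0.269 with an estimated correlation). FOSL1, an AP-1 subunit, fell from 572 ± 18.8 to 34.5 ± 1.39 CPM (-4.05 ± 0.18 log2), MAFF fell (-2.85 ± 0.11) and ATF3, a stress-response factor, rose (1.15 ± 0.11). Of 19 other ERK negative feedback genes, 9 fell, 5 rose and 5 were not called (11 fell and 5 rose adjusted over the list alone; median -0.44, adjusted p = 0.0122, and adjusted p = 0.0622 with an estimated correlation). SPRED3 (-2.27 ± 0.18) and TRIB2 (-2.23 ± 0.14) were among those that fell.

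The RAS-RAF-MEK-ERK members themselves went both ways in KHM-5M. Of 13 members, 3 rose, 4 fell and 6 were not called (4 rose and 5 fell adjusted over the list alone), and the list was not called (median -0.03, adjusted p = 0.549). BRAF rose (0.50 ± 0.12), while KSR1, a scaffold of the cascade (-0.94 ± 0.14), HRAS (-0.83 ± 0.09) and MAP2K1, which encodes MEK1 (-0.79 ± 0.07), fell. The BRAF call was lost when the length and GC trend of each library was removed (adjusted p = 0.178). MAPK3, which encodes an ERK kinase (0.35 ± 0.12), lost its call without KHM-5M DMSO replicate 1 (adjusted p = 0.0654) or 2 (0.0661), or GDC-0994 replicate 1 (0.0618) or 2 (0.0626). RPS6KA1, which encodes an ERK-activated kinase (-0.28 ± 0.09), lost its call without DMSO replicate 1 (adjusted p = 0.0805), 2 (0.103) or 3 (0.0677), or GDC-0994 replicate 2 (0.0691) or 3 (0.158). NRAS (0.30 ± 0.12) was not called, and was called without GDC-0994 replicate 1 (adjusted p = 0.00763), with DESeq2 size factors (0.0345), the DESeq2 Wald test (0.0354), the stricter filter (0.0435) or only the KHM-5M libraries (0.0315), and after removal of the length and GC trend (0.00757). Over all alternatives the adjusted p ranged from 8.45e-05 to 0.178 for BRAF, 2.86e-05 to 0.0661 for MAPK3, 9.83e-04 to 0.158 for RPS6KA1 and 0.00757 to 0.151 for NRAS.

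Cell cycle genes fell in KHM-5M. All 39 members of the DNA replication and E2F list fell (39 adjusted over the list alone; median -2.51, adjusted p = 2.13e-102), as did all 34 of the mitosis list (34 adjusted over the list alone; median -2.08, adjusted p = 2.32e-69). MCM4, a subunit of the replicative helicase, fell from 504 ± 15.5 to 74.7 ± 4.43 CPM (-2.75 ± 0.07), and CDC6, which loads that helicase, from 84.5 ± 1.90 to 11.5 ± 0.912 CPM (-2.88 ± 0.08). TPX2, a spindle assembly factor (-2.21 ± 0.06), and UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex (-2.60 ± 0.08), fell too. In the cell cycle arrest and quiescence list, 15 of 22 members rose and 4 fell (15 and 4 adjusted over the list alone; median 0.90, adjusted p = 2.05e-05). CITED2, a transcriptional coregulator, rose from 69.2 ± 4.24 to 602 ± 36.8 CPM (3.12 ± 0.09), and the CDK inhibitor genes CDKN2B (2.66 ± 0.09) and CDKN1A (1.03 ± 0.10) rose, while CDKN2C (-1.51 ± 0.11) fell. Of 10 replication-dependent histone genes 7 rose and none fell (7 rose adjusted over the list alone; median 1.49, adjusted p = 9.29e-06), among them HIST1H2AC (1.95 ± 0.11) and HIST1H1C (1.79 ± 0.12). Many histone transcripts are close in sequence and most lack poly(A) tails, so the counts cover the polyadenylated part. In the ribosome biogenesis and MYC targets list, 29 of 32 members fell and none rose (29 adjusted over the list alone; median -0.75, adjusted p = 3.80e-09), among them NOP56 (-1.24 ± 0.08) and DKC1 (-1.13 ± 0.07), which act in small nucleolar RNA complexes.

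Among the 10 rises selected in KHM-5M, CRISPLD2, a secreted protein (ENSG00000103196, chromosome 16, 84819984 to 84920768), rose from 2.80 ± 0.350 to 74.0 ± 4.02 CPM (4.72 ± 0.15, adjusted p = 2.25e-13). GREM1, a BMP antagonist, rose from 53.3 ± 2.18 to 1356 ± 93.2 CPM (4.67 ± 0.09), and the matrix protease ADAMTS5 from 1.68 ± 0.0648 to 43.3 ± 2.17 CPM (4.68 ± 0.15). BMF, a pro-apoptotic BCL2 family member, rose from 8.56 ± 2.17 to 179.9 ± 18.5 CPM (4.39 ± 0.16), TP53INP1 rose (3.57 ± 0.13) and IL7R, the interleukin 7 receptor, rose (3.51 ± 0.09). PPL (4.06), OLFML3 (3.94), ACKR3 (3.58) and COL9A2 (3.45) completed the selected rises. TGM2, a transglutaminase (ENSG00000198959, chromosome 20, 38127387 to 38166578), fell from 2212 ± 76.9 to 159 ± 14.2 CPM (-3.80 ± 0.10, adjusted p = 5.96e-14). SLCO4A1 (-4.89), MYEOV (-4.56), SIGLEC15 (-4.33), G0S2 (-3.81) and WNT7B (-3.74) were among the other selected falls.

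Stress, lysosomal, interferon and matrix genes also moved in KHM-5M. In the NRF2 targets and ferroptosis list, 17 of 25 members rose and none fell (17 adjusted over the list alone; median 0.55, adjusted p = 1.94e-07). FTL, the ferritin light chain, rose from 3949 ± 81.3 to 12070.2 ± 603 CPM (1.61 ± 0.07) and took 1.27 ± 0.0419% of the counts with GDC-0994 against 0.404 ± 0.00922% with DMSO. AKR1C3, an aldo-keto reductase, rose as well (2.24 ± 0.07). Of 30 interferon response genes 23 rose and 2 fell (23 and 2 adjusted over the list alone; median 0.65, adjusted p = 0.00178, and adjusted p = 0.0711 with an estimated correlation), with rises of IFI27 (1.32 ± 0.10) and STAT2 (1.10 ± 0.10) and a fall of OAS3 (-1.15 ± 0.08). Of 29 lysosome and autophagy genes 17 rose and 5 fell (19 and 6 adjusted over the list alone; median 0.37, adjusted p = 0.00550, and adjusted p = 0.151 with an estimated correlation), including rises of the autophagy receptor SQSTM1 (1.06 ± 0.06) and the sialidase NEU1 (1.32 ± 0.08). Among 27 mesenchymal and matrix genes 13 rose and 8 fell (13 and 8 adjusted over the list alone; median 0.31, adjusted p = 0.00794, and adjusted p = 0.247 with an estimated correlation). MMP2, a matrix metalloproteinase, rose from 88.4 ± 6.56 to 428 ± 26.5 CPM (2.27 ± 0.10). Of 19 epithelial genes 11 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.50, adjusted p = 0.0206, and adjusted p = 0.247 with an estimated correlation). The epithelial transcription factor ELF3 rose from 0.362 ± 0.0697 to 6.60 ± 1.11 CPM (4.16 ± 0.27), MUC1 rose (1.89 ± 0.21) and CLDN1, a tight junction protein, fell (-0.84 ± 0.10).

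In the serine, one-carbon and ATF4 targets list, 18 of 30 members fell and 5 rose in KHM-5M (18 and 6 adjusted over the list alone; median -0.48, adjusted p = 0.00408, and adjusted p = 0.272 with an estimated correlation). PSAT1, an enzyme of serine synthesis (-1.17 ± 0.07), and MTHFD1, an enzyme of folate metabolism (-1.12 ± 0.06), fell. Of 25 cytokines and NF-kB targets 7 fell and 3 rose (7 and 3 adjusted over the list alone; median -0.21, adjusted p = 0.0399, and adjusted p = 0.269 with an estimated correlation), with falls of IL11 (-2.81 ± 0.15) and PLAU, the urokinase gene (-1.98 ± 0.07). The call of this list was lost without KHM-5M DMSO replicate 3 (median -0.05, adjusted p = 0.0593) or GDC-0994 replicate 3 (median -0.18, adjusted p = 0.0611), after removal of the length and GC trend (adjusted p = 0.229), with the stricter filter, where the median turned to 0.022 (adjusted p = 0.113), and with a replicate block (adjusted p = 0.0920), over a range of 2.01e-05 to 0.269 for all alternatives.

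Across all genes tested in KHM-5M, 3991 rose and 4078 fell, 8069 together or 49.8% of those tested. The balance turned with the scaling: 4294 rose and 3807 fell with DESeq2 size factors, 4716 and 3576 with upper quartile scaling, and 4432 and 3737 with library totals. After removal of the length and GC trend it kept its direction, with 4090 up and 4836 down. Of the 8069 genes, 2598 had an absolute log2 fold change of at least 1, 1272 up and 1326 down. With a replicate block the count was 7849. Of the 31 lists 15 were called in KHM-5M, and 7 of these calls held with an estimated correlation: MAPK output, DNA replication and E2F, mitosis, cell cycle arrest and quiescence, ribosome biogenesis and MYC targets, NRF2 targets and ferroptosis genes, and replication-dependent histones.

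**Figure D2:**
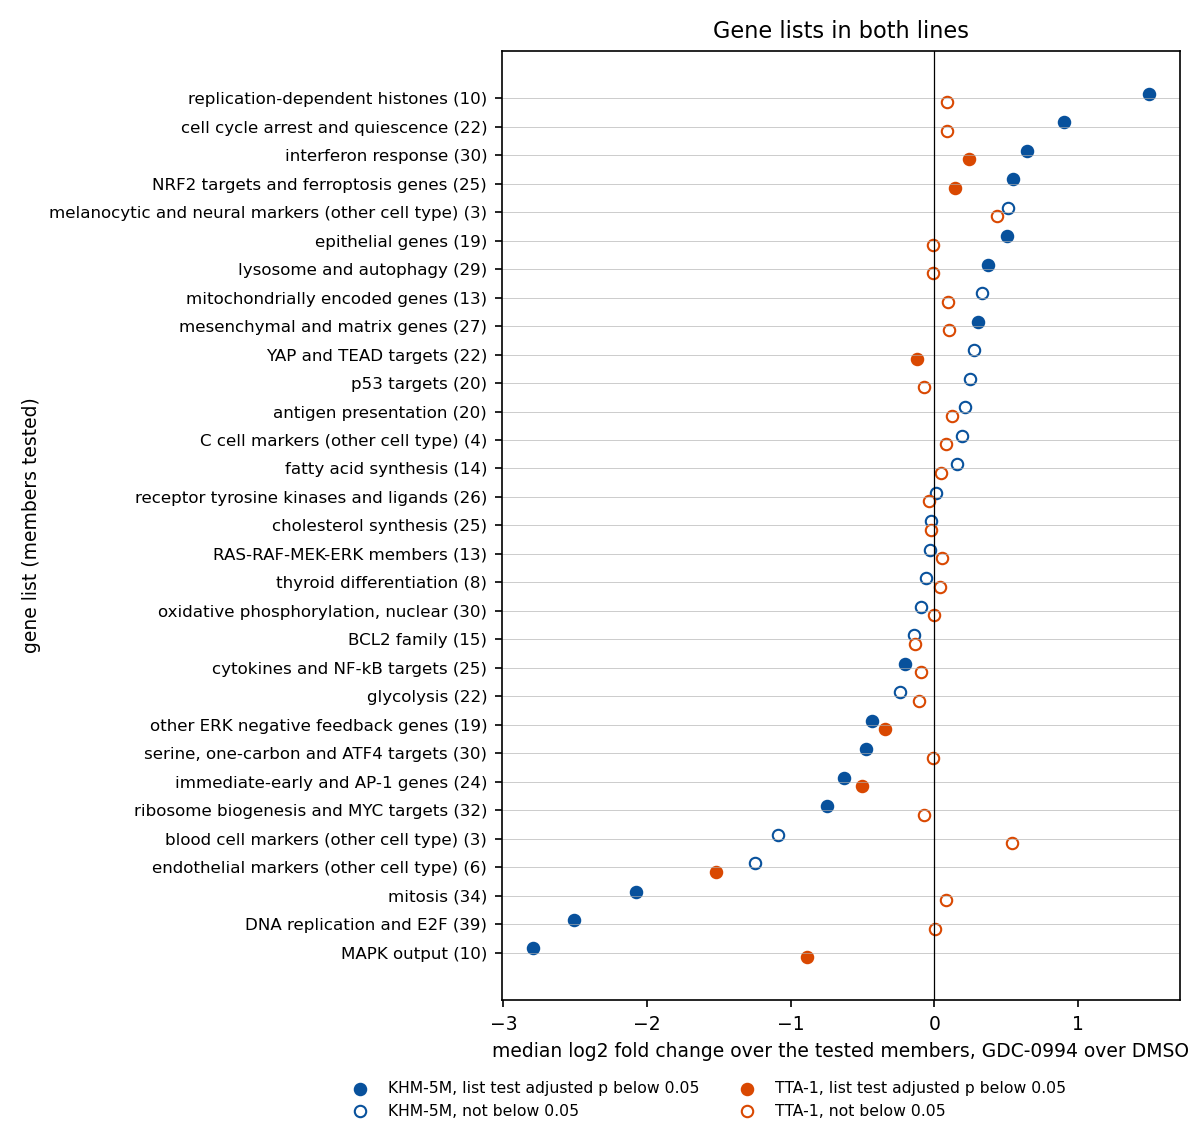
Median log2 fold change, GDC-0994 over DMSO, of each gene list (tested members in brackets) in KHM-5M and TTA-1, with filled circles where the list test had an adjusted p below 0.05. MAPK output lies at -2.80 in KHM-5M and -0.89 in TTA-1, and DNA replication and E2F at -2.51 and 0.01; the endothelial medians include members near 0 counts.

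The comparison of GDC-0994 with DMSO in TTA-1 asked the same in a line labelled BRAF wild type. ERK-responsive genes fell here too. In the MAPK output list 8 of 10 members fell and none rose (9 fell adjusted over the list alone; median -0.89, adjusted p = 4.51e-44). PHLDA1 (ENSG00000139289, chromosome 12, 76025447 to 76033932) fell from 90.6 ± 6.87 to 26.6 ± 2.08 CPM (-1.77 ± 0.08, adjusted p = 9.13e-10). SPRY4, an inhibitor of receptor signalling (-1.74 ± 0.16), ETV4 (-1.19 ± 0.12), ETV5 (-0.96 ± 0.10), EPHA2 (-0.82 ± 0.08) and CCND1 (-0.70 ± 0.07) fell as well. DUSP6 fell from 2.54 ± 0.381 to 0.602 ± 0.534 CPM (-2.05 ± 0.40, and -2.89 without GDC-0994 replicate 2). DUSP4 fell (-0.52 ± 0.11), a call that was lost without GDC-0994 replicate 3 (adjusted p = 0.0717). With only the TTA-1 libraries in the model, neither DUSP4 (adjusted p = 0.0566) nor DUSP6 (adjusted p = 0.0900) passed, and over all alternatives their adjusted p ranged from 3.49e-04 to 0.0717 and from 3.32e-07 to 0.0900. SPRY2 (-0.39 ± 0.15) and EPHA4 (0.68 ± 0.76) were not called. The mean log2(CPM + 1) over the list was 4.68 ± 0.02 in DMSO and 3.82 ± 0.14 in GDC-0994, a difference of -0.86 (exact permutation test of both sides, p = 0.1, the smallest possible).

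Immediate-early and feedback genes fell with them in TTA-1. Of 24 immediate-early and AP-1 genes 13 fell and none rose (15 fell adjusted over the list alone; median -0.51, adjusted p = 3.70e-28). EGR1 (ENSG00000120738, chromosome 5, 138465490 to 138469315), a zinc finger factor, fell from 16.3 ± 1.79 CPM to 0.0445 ± 0.0385 CPM, or from 758 counts to 2, a ratio of 363 (95% counting interval 100.1 to 3001). MAFF (-1.71 ± 0.13) and FOSL1 (-1.59 ± 0.17) fell. The TTA-1 DMSO libraries differed on this list, with a median log2 ratio to the other TTA-1 DMSO libraries of 0.24 in replicate 1 and -0.30 in replicate 2 over 17 of its genes. Of 19 other ERK negative feedback genes 8 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.34, adjusted p = 8.95e-10). DUSP5, a nuclear ERK phosphatase, fell from 34.7 ± 3.02 to 7.58 ± 1.49 CPM (-2.19 ± 0.16), and PHLDA2 (-1.33 ± 0.17) and the cytokine gene LIF (-0.61 ± 0.11) fell. DUSP8 rose (1.23 ± 0.30), a call that was lost without DMSO replicate 3 (adjusted p = 0.113) or GDC-0994 replicate 1 (0.139) or 3 (0.0522), with only the TTA-1 libraries (0.192) and with limma on log2(FPKM + 1) (0.139), with a range of 0.00140 to 0.192 over all alternatives. With only the TTA-1 libraries in the model LIF was not called (adjusted p = 0.0596, range 3.65e-05 to 0.0596).

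The lists of DNA replication and mitosis genes were not called in TTA-1. The DNA replication and E2F list had a median of 0.01 (adjusted p = 0.997), where the list test pointed down and the median up. None of its 39 members passed in edgeR, with 3 at an unadjusted p under 0.05, 0 in DESeq2, 0 in limma on FPKM and 0 after removal of the length and GC trend. CDC6 had 442 ± 25.4 CPM in DMSO and 459.8 ± 1.47 CPM in GDC-0994, and MCM4 499 ± 10.1 and 515 ± 2.85 CPM. The mitosis list had a median of 0.08 (adjusted p = 0.105), and none of its 34 members passed in edgeR, with 8 at an unadjusted p under 0.05, 1 in DESeq2, 0 in limma on FPKM and 3 after removal of the trend. UHRF1 (-0.22 ± 0.08) of the former list and CENPE (0.54 ± 0.16) of the latter were not called, and both passed without TTA-1 DMSO replicate 2 (adjusted p = 0.0135 and 0.00135, ranges 0.0135 to 0.495 and 0.00116 to 0.237). CENPE also passed with the DESeq2 Wald test (adjusted p = 0.0392) and after removal of the trend (0.00116). None of the 13 RAS-RAF-MEK-ERK members passed in edgeR (0 adjusted over the list alone; median 0.05, adjusted p = 0.997), with 2 at an unadjusted p under 0.05, 0 in DESeq2 and 0 in limma on FPKM. After removal of the trend 1 passed, RPS6KA1 (0.30, adjusted p = 0.00519, range 0.00519 to 0.557). Without TTA-1 DMSO replicate 2, NRAS (0.34, adjusted p = 0.0210) and MAP2K2 (-0.38, adjusted p = 0.0123) passed, with ranges of 0.0210 to 0.879 and 0.0123 to 0.985. The ribosome biogenesis and MYC targets list was not called (median -0.07, adjusted p = 0.0681), and was called without TTA-1 DMSO replicate 2 (adjusted p = 0.0312, range 0.0312 to 0.4998). None of its 32 members passed in edgeR, with 7 at an unadjusted p under 0.05, 0 in DESeq2, 0 in limma on FPKM and 0 after removal of the trend. CDKN1A, the p21 gene, fell from 15.8 ± 0.992 to 7.35 ± 0.937 CPM (-1.10 ± 0.12, adjusted p = 2.77e-05).

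In TTA-1, NT5E (ENSG00000135318, chromosome 6, 85449584 to 85495791), an ectonucleotidase on the YAP and TEAD targets list, fell from 20.8 ± 2.62 to 4.42 ± 0.524 CPM (-2.23 ± 0.12, adjusted p = 7.13e-09), and the receptor kinase gene AXL fell (-0.54 ± 0.07). In that list 7 of 22 members fell and 1, RBMS3 (1.31 ± 0.21), rose (10 and 1 adjusted over the list alone; median -0.12, adjusted p = 2.25e-06). TGM2 fell (-2.17 ± 0.10), and KCNJ12 (-1.65 ± 0.13), MYEOV (-1.55 ± 0.12) and the ubiquitin ligase gene MARCH4 (-1.53 ± 0.11) fell. Of the 25 NRF2 targets and ferroptosis genes 4 rose and none fell (8 rose and 1 fell adjusted over the list alone; median 0.15, adjusted p = 2.51e-06), and without TTA-1 DMSO replicate 2 the median was 0.04 (adjusted p = 6.3e-04). AKR1C2 rose from 720.3 ± 12.6 to 1299.6 ± 62.8 CPM (0.85 ± 0.09) and AKR1B10 rose (1.01 ± 0.12); AKR1C2 shares much of its sequence with AKR1C1. Of 30 interferon response genes 2 rose and none fell (10 rose adjusted over the list alone; median 0.24, adjusted p = 1.30e-05), namely IFI44L (0.89 ± 0.17) and IFIH1 (0.72 ± 0.15). The IFIH1 call was lost without TTA-1 DMSO replicate 1 (adjusted p = 0.0556) or 3 (0.0609) or GDC-0994 replicate 2 (0.0610), with a range of 5.70e-04 to 0.0610 over all alternatives. ZSCAN31 (1.33 ± 0.13), the complement gene C3 (1.30 ± 0.14), SAMD9L (1.23 ± 0.24) and ITGB8 (1.18 ± 0.22) rose. ITGB8 lost its call with limma on log2(FPKM + 1) (adjusted p = 0.357, range 2.15e-05 to 0.357).

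Several of the selected TTA-1 rises were not called when single libraries were left out. SLC12A3 (1.67) lost its call without DMSO replicate 3 (adjusted p = 0.0538) or GDC-0994 replicate 2 (0.0683), SUSD2 (1.196) without GDC-0994 replicate 1 (0.0776), and BMF (1.19) without GDC-0994 replicate 2 (0.0573). WISP2 (1.28) lost its call without DMSO replicate 1 (0.0956) or 3 (0.140) or GDC-0994 replicate 1 (0.146), 2 (0.0837) or 3 (0.176). HRCT1 (1.26) lost its call without DMSO replicate 1 (0.0903) or 3 (0.128) or GDC-0994 replicate 2 (0.181) or 3 (0.196), and with a replicate block (0.0643). With only the TTA-1 libraries in the model SUSD2 (adjusted p = 0.0776), BMF (0.0574) and HRCT1 (0.123) were not called, nor was BMF with limma on log2(FPKM + 1) (0.0850). Over all alternatives the adjusted p ranged from 7.24e-04 to 0.0683 for SLC12A3, 8.52e-04 to 0.0776 for SUSD2, 5.46e-05 to 0.0850 for BMF, 0.00999 to 0.176 for WISP2 and 0.00743 to 0.196 for HRCT1.

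Across all genes tested in TTA-1, 192 rose and 364 fell, 556 together or 3.43%, and 116 of them had an absolute log2 fold change of at least 1. Leaving out 1 library gave 349 (DMSO replicate 1), 2620 (DMSO replicate 2), 311 (DMSO replicate 3), 442 (GDC-0994 replicate 1), 311 (GDC-0994 replicate 2) or 259 (GDC-0994 replicate 3), and a replicate block gave 529. The count was 915 with DESeq2, 1206 without the filter, 206 with only the TTA-1 libraries in the model, 341 with limma on unfiltered FPKM, and 963 (489 up, 474 down) after removal of the length and GC trend. Of the 31 lists 7 were called in TTA-1, and 6 of these calls held with an estimated correlation, all except the endothelial markers.

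**Figure D3:**
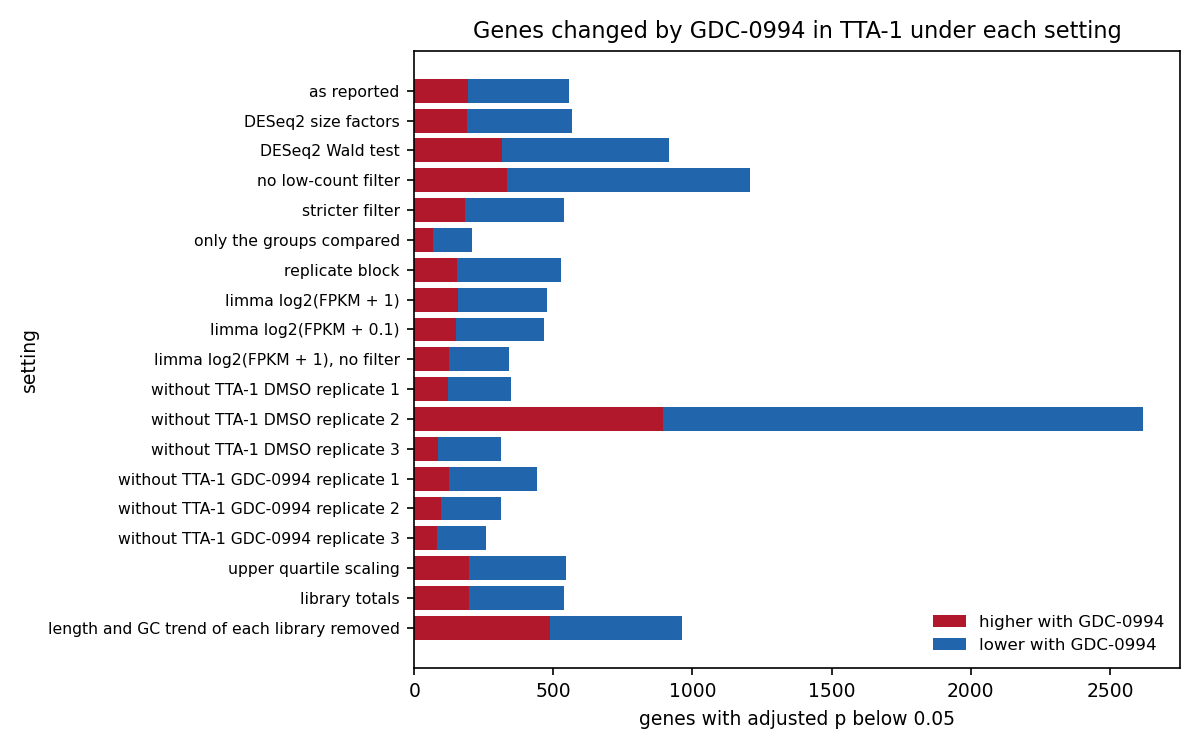
Genes with adjusted p below 0.05 for GDC-0994 in TTA-1 under each setting, split into higher (red) and lower (blue) with GDC-0994; the horizontal axis starts at 0. The count was 556 as reported and ranged from 206 with only the groups compared to 2620 without TTA-1 DMSO replicate 2.

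The difference of the 2 treatment effects, KHM-5M minus TTA-1, asked whether the lines responded unequally. ERK output genes fell further in KHM-5M, and cell cycle genes had lower log2 fold changes there. In the MAPK output list 9 of 10 members had a lower log2 fold change in KHM-5M (9 lower and 1 higher adjusted over the list alone; median difference -2.05, adjusted p = 4.72e-16), among them ETV4 (-4.01 ± 0.19), ETV5 (-2.90 ± 0.16), SPRY2 (-2.47 ± 0.19) and DUSP4 (-2.12 ± 0.19). The DUSP6 difference (-2.06 ± 0.54, adjusted p = 0.00891) was not called without TTA-1 GDC-0994 replicate 2 (-1.1997, adjusted p = 0.217, range 4.79e-07 to 0.217 over all alternatives). EPHA4 was not called (2.52 ± 1.10), and was called without TTA-1 DMSO replicate 1 (adjusted p = 0.0464) or 2 (adjusted p = 0.0418, range 0.0418 to 0.766). All 39 DNA replication and E2F genes (39 adjusted over the list alone; median -2.44, adjusted p = 2.44e-147) and all 34 mitosis genes (34 adjusted over the list alone; median -2.22, adjusted p = 2.85e-102) had a lower log2 fold change in KHM-5M, among them MCM4 (-2.80 ± 0.09), CDC6 (-2.94 ± 0.10), TPX2 (-2.26 ± 0.08) and UBE2C (-2.48 ± 0.11). In the ribosome biogenesis and MYC targets list 26 of 32 members were lower (27 lower and 1 higher adjusted over the list alone; median -0.61, adjusted p = 5.39e-09), among them NOP56 (-1.23 ± 0.11). Of the cell cycle arrest and quiescence genes 8 of 22 were higher and 4 lower (11 and 4 adjusted over the list alone; median 0.62, adjusted p = 5.08e-04). CDKN1A rose in KHM-5M and fell in TTA-1 (2.12 ± 0.15, adjusted p = 1.81e-08), and TXNIP differed by 2.23 ± 0.13.

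Other lists also differed in response. Log2 fold changes were higher in KHM-5M for 7 of 10 replication-dependent histones (7 adjusted over the list alone; median 1.37, adjusted p = 1.89e-06) and for 14 of 25 NRF2 targets and ferroptosis genes, with 1 lower (15 and 1 adjusted over the list alone; median 0.38, adjusted p = 5.83e-07), with FTL at 1.63 ± 0.10 and AKR1C3 at 1.77 ± 0.10. Of 22 YAP and TEAD targets 10 were higher and 5 lower (11 and 5 adjusted over the list alone; median 0.30, adjusted p = 0.00106), with TGFB2 at 2.54 ± 0.15, AJUBA at 1.25 ± 0.10 and NT5E at -1.01 ± 0.15. The lysosome and autophagy list (15 of 29 higher, 2 lower; 15 and 4 adjusted over the list alone) had a median difference of 0.34 (adjusted p = 0.00129, and adjusted p = 0.0997 with an estimated correlation), with SQSTM1 at 1.03 ± 0.08. The epithelial list (9 of 19 higher, 1 lower; 11 and 1 adjusted over the list alone) had a median difference of 0.42 (adjusted p = 0.00710, and adjusted p = 0.165 with an estimated correlation), with ELF3 at 3.91 ± 0.33. That median was 0.66 without KHM-5M GDC-0994 replicate 3, 0.71 and 0.64 without TTA-1 DMSO replicates 2 and 3, and 0.65 without TTA-1 GDC-0994 replicate 2. The serine, one-carbon and ATF4 targets list (2 of 30 higher, 15 lower; 3 and 18 adjusted over the list alone) had a median of -0.41 (adjusted p = 0.00106, and adjusted p = 0.295 with an estimated correlation), with PSAT1 at -1.27 ± 0.10 and ATF3 at 1.16 ± 0.15. Selected genes with a higher log2 fold change in KHM-5M included CRISPLD2 (4.79 ± 0.22), PPL (3.95 ± 0.28), IL7R (3.51 ± 0.11) and RARRES2 (3.15 ± 0.26), and those with a lower one KCNK3 (-4.33 ± 0.30), SLCO4A1 (-4.24 ± 0.16), E2F2 (-3.35 ± 0.20) and SPC24 (-3.33 ± 0.16). RAD54L (-3.26 ± 0.16) shares 25.1% of its exon bases with LRRC41, and the counts carry no strand information. The RAS-RAF-MEK-ERK members (median -0.06, adjusted p = 0.558), the immediate-early and AP-1 genes (median -0.08, adjusted p = 0.928), the other ERK negative feedback genes (median -0.02, adjusted p = 0.857) and the interferon response (median 0.31, adjusted p = 0.324) were not called for a difference, and for the immediate-early and feedback lists the median, mean and test differed in sign.

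A difference between the lines' responses was called for 4527 genes (27.9%), 1995 with a higher and 2532 with a lower log2 fold change in KHM-5M, and for 1739 it was at least 1 on the log2 scale. With upper quartile scaling 2403 were higher and 2208 lower, and after removal of the length and GC trend 2278 and 3498. With a replicate block the count was 4225. Of 11 lists called for a difference, 8 held with an estimated correlation, all except the lysosome, epithelial and serine lists. The called genes overlapped between lines. Among genes higher with GDC-0994, 124 were called in both lines against 47.2 expected (Fisher's exact test, one-sided, p = 6.11e-32), and among genes lower 220 against 91.5 (p = 4.20e-47). The test takes genes as independent draws, which they are not. Both sets of calls also come from 1 model that shares each gene's spread between the lines. Genes with a low spread can be called in both for that reason, so the expected counts may be too low. The p-values are therefore not a measure of chance overlap. Another 62 genes were called in opposite directions, against 344 in the same direction, and 150 in TTA-1 without a call in KHM-5M. Log2 fold changes of the lines had a Pearson correlation of 0.19 and a Spearman correlation of 0.23 across genes, which are not independent replicates. The 344 shared calls in the same direction became 1388 without TTA-1 DMSO replicate 2, 206 without DMSO replicate 3, 213 and 185 without TTA-1 GDC-0994 replicates 2 and 3, and 586 after removal of the length and GC trend.

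**Figure D4:**
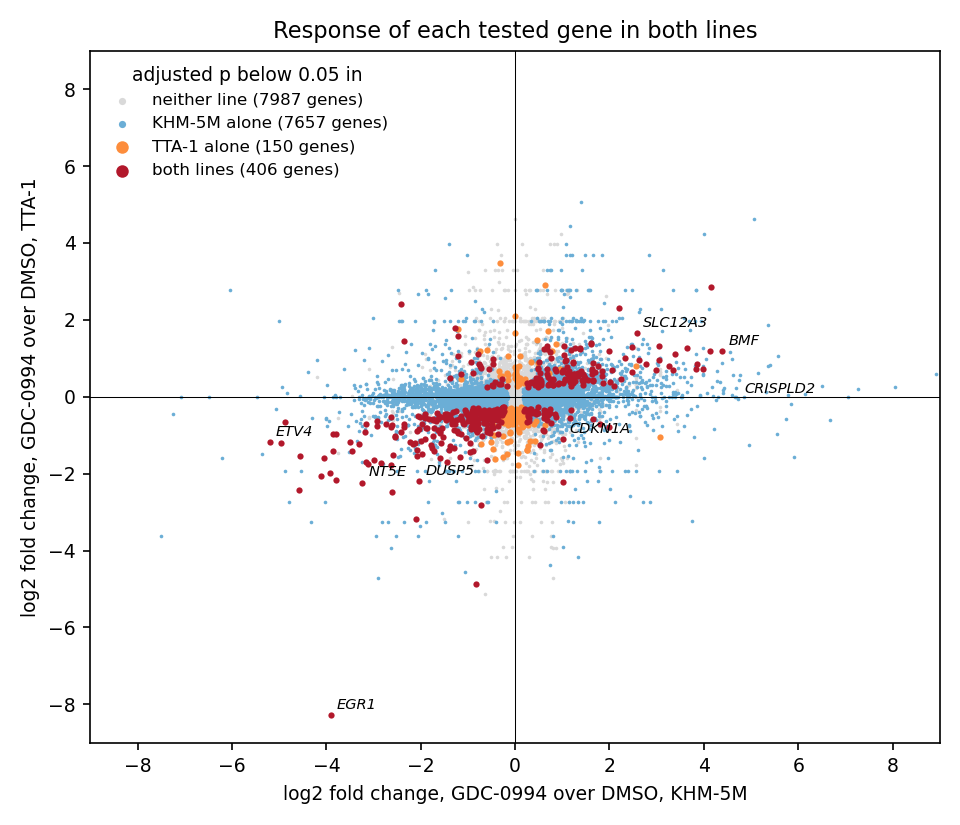
Log2 fold change, GDC-0994 over DMSO, of each tested gene in KHM-5M (horizontal) and TTA-1 (vertical), coloured by the line in which the adjusted p lay below 0.05; Y-linked genes and the X inactivation transcripts are not drawn, and points in horizontal bands are genes near 0 counts in TTA-1. The spread is wider along the KHM-5M axis, and EGR1, NT5E and DUSP5 lie low in both lines while CDKN1A lies right of 0 and below 0.

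The comparison of the DMSO groups, KHM-5M over TTA-1, described the lines before treatment, which also differed in medium. Matrix genes were higher in KHM-5M, with 17 of 27 mesenchymal and matrix genes higher and 4 lower (17 and 4 adjusted over the list alone). The list had a median of 1.19, or 1.01 without 1 member under the floor (list test, adjusted p = 2.02e-10). FN1, which encodes fibronectin, had 3904 ± 189 CPM in KHM-5M and 1.73 ± 0.276 CPM in TTA-1 (11.14 ± 0.13), and SPARC was higher by 7.54 ± 0.12. NRF2 targets and ferroptosis genes were lower in KHM-5M, 19 of 25 against 1 higher (19 and 1 adjusted over the list alone; median -0.94, adjusted p = 2.86e-15), among them AKR1C1 with 2.95 ± 0.422 CPM in KHM-5M and 1326 ± 24.4 CPM in TTA-1 (-8.81 ± 0.10). Ribosome biogenesis and MYC targets were lower as well, 28 of 32 with none higher (28 adjusted over the list alone; median -1.17, adjusted p = 8.02e-08), among them WDR43 (-2.11 ± 0.08) and ODC1 (-1.77 ± 0.06), and MYC itself was lower (-2.57 ± 0.09). Of 19 epithelial genes 11 were lower and 5 higher (11 and 5 adjusted over the list alone; median -1.35, adjusted p = 0.00674, and adjusted p = 0.182 with an estimated correlation), with KRT7, a keratin of simple epithelia, at 69.8 ± 1.91 CPM in KHM-5M and 851 ± 91.5 CPM in TTA-1, and KRT19 higher in KHM-5M (3.29 ± 0.41). That median was -0.85 and -0.84 without KHM-5M DMSO replicates 1 and 3, and -0.85, -0.88 and -0.83 without TTA-1 DMSO replicates 1, 2 and 3.

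In the MAPK output list 6 of 10 members were higher and 2 lower in KHM-5M than in TTA-1 in DMSO (6 and 2 adjusted over the list alone; median 1.32, adjusted p = 0.0417, and adjusted p = 0.373 with an estimated correlation). SPRY2 (4.32 ± 0.12) and DUSP6 (3.70 ± 0.24) were higher, DUSP4 (-2.04 ± 0.11) and EPHA2 (-0.87 ± 0.08) lower, and ETV5 was not called (0.01 ± 0.10). The list lost its call without KHM-5M DMSO replicate 1 (adjusted p = 0.0503) or TTA-1 DMSO replicate 1 (adjusted p = 0.0646), and with a replicate block (adjusted p = 0.110), and over all alternatives its adjusted p ranged from 3.31e-07 to 0.373. BRAF (ENSG00000157764, chromosome 7, 140719327 to 140924928) had 21.8 ± 1.46 CPM in KHM-5M and 21.8 ± 2.36 CPM in TTA-1 (0.00 ± 0.12, not called). HRAS (1.22 ± 0.10) and MAPK3 (1.83 ± 0.13) were higher, and NRAS (-1.57 ± 0.13) and ARAF (-1.71 ± 0.10) lower, within a list of 13 with 4 higher and 6 lower (4 and 6 adjusted over the list alone; median -0.14, adjusted p = 0.723). Cell cycle arrest and quiescence genes were higher in KHM-5M, 13 of 22 against 4 lower (13 and 4 adjusted over the list alone; median 0.55, adjusted p = 0.0336, and adjusted p = 0.158 with an estimated correlation), with CDKN2B at 6.74 ± 0.20 and CDKN1C at 5.32 ± 0.20, while GAS1 was lower (-2.36 ± 0.47). With a replicate block that list (adjusted p = 0.0612) and the epithelial list (adjusted p = 0.0501) were not called. Of 8 thyroid differentiation genes 5 were higher and 2 lower (5 and 2 adjusted over the list alone; median 1.64, adjusted p = 0.8995), and the list was not called. PAX8, a thyroid transcription factor, had 210.2 ± 8.69 CPM in KHM-5M and 3.59 ± 0.552 in TTA-1, and DIO2, a deiodinase, 0.153 ± 0.0676 CPM in KHM-5M and 423 ± 20.4 CPM in TTA-1. MET, the hepatocyte growth factor receptor, had 138 ± 4.23 CPM in KHM-5M and 5827 ± 1051 CPM in TTA-1.

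Among genes selected for the largest differences in DMSO, most had no count in 1 of the lines, so only lower bounds against a floor of 3 counts per library can be given. In KHM-5M the metallothionein gene MT1E was at least 1241-fold higher, the potassium channel gene KCNMA1 at least 745-fold and the cadherin gene CDH13 at least 411-fold. The cancer-testis genes MAGEC2 and MAGEA10 were at least 395-fold higher there. In TTA-1 the carboxylesterase gene CES1 was at least 1482-fold higher, OLR1 at least 541-fold, OLFM1 at least 266-fold and SERPINB2 at least 143-fold. FBLN2, a matrix protein gene, had 2 counts in the KHM-5M group and 7411 in the TTA-1 group, a ratio of 4193 (95% counting interval 1160.3 to 34627). MT1E, the MAGE genes and AKR1C1 have close paralogs, and reads shared with them were not resolved. Of all genes tested, 6430 were higher and 5975 lower in KHM-5M, 12405 together or 76.5%, and 7126 differed by at least 1 on the log2 scale. With a replicate block the count was 11396. The median log2 difference of all genes was 0.03, and 0.13 with upper quartile scaling or library totals. Of 7 lists called, the mesenchymal, NRF2 and ribosome lists held with an estimated correlation.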

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

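The test of the starting level, the thinning to equal totals, and the upper quartile and library total scalings were chosen only after the results were seen. The responses to GDC-0994 differed between the lines for 4527 genes by the edgeR test of the difference (KHM-5M minus TTA-1). They also differed for 11 lists by the list test, whose median log2 differences were -2.05 for MAPK output, -2.44 for DNA replication and E2F, -2.22 for mitosis, -0.61 for ribosome biogenesis and MYC targets, -0.41 for the serine, one-carbon and ATF4 targets, 0.62 for cell cycle arrest and quiescence, 0.34 for lysosome and autophagy, 0.42 for epithelial genes, 0.30 for YAP and TEAD targets, 0.38 for NRF2 targets and ferroptosis genes, and 1.37 for replication-dependent histones. The serine, lysosome and epithelial calls were lost with an estimated correlation (adjusted p = 0.295, 0.0997 and 0.165). Of 100 relabellings of libraries within lines that were drawn, 5 gave as many called genes as the real labels, the real ones included, and the highest of the others was 5653. All 5 kept the KHM-5M groups and so the KHM-5M response, while the 91 that broke those groups put that response into the spread between libraries, so the relabelling does not decide whether chance can be excluded for the count of 4527. Data simulated without changes gave 2 calls, but they held no trends of whole libraries and an equal spread in both lines. They do not give the rate of false calls in the real libraries.

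Each named gene listed here passed the test of the difference, and the value in brackets is its log2 difference in response. Lower and higher refer here to the log2 fold change with GDC-0994 in KHM-5M against that in TTA-1, not to expression levels. The log2 fold change was lower in KHM-5M for the ERK pathway and output genes ETV4 (-4.01), ETV5 (-2.90), SPRY2 (-2.47), SPRY4 (-1.39), DUSP4 (-2.12), DUSP6 (-2.06), CCND1 (-2.04), PHLDA1 (-0.86), EPHA2 (-0.73), FOSL1 (-2.46), MAFF (-1.14), HRAS (-0.69), KSR1 (-0.78), MAP2K1 (-0.62) and RPS6KA1 (-0.48). The DUSP6 difference was not called without TTA-1 GDC-0994 replicate 2 (-1.1997, adjusted p = 0.217, range 4.79e-07 to 0.217 over all alternatives). The RPS6KA1 difference was not called without KHM-5M DMSO replicate 2 (adjusted p = 0.0565), KHM-5M GDC-0994 replicate 3 (0.0608) or TTA-1 GDC-0994 replicate 2 (0.0603), with a range of 2.84e-05 to 0.0608. Lower among cell cycle genes were MCM4 (-2.80), CDC6 (-2.94), UHRF1 (-2.51), E2F2 (-3.35), TPX2 (-2.26), UBE2C (-2.48), CENPE (-2.31), SPC24 (-3.33), RAD54L (-3.26), FAM111B (-3.55) and CDKN2C (-1.68), and FAM111B was at -4.71 without KHM-5M GDC-0994 replicate 3. Lower among metabolic, ribosome biogenesis and mitochondrial genes were NOP56 (-1.23), DKC1 (-1.05), PSAT1 (-1.27), MTHFD1 (-1.06), ALDH1L2 (-1.22), ENO2 (-0.94), CYC1 (-0.43) and MT-ATP8 (-1.84). MT-ATP8, which rose in TTA-1 and fell in KHM-5M, shares 22.2% of its exon bases with MT-ATP6. Lower among surface, secreted and other genes were TGM2 (-1.63), NT5E (-1.01), MYEOV (-3.01), SLCO4A1 (-4.24), KCNK3 (-4.33), WNT7B (-3.35), G0S2 (-2.85), PLAU (-1.86), PLAUR (-0.61), MET (-1.06), CLDN1 (-0.83), PAX8 (-0.83), BCL2 (-2.16), PLK3 (-0.77), OAS3 (-1.33), TAP2 (-0.93), LAPTM5 (-1.63), ROBO4 (-0.81) and MARCH4 (-0.54).

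The log2 fold change was higher in KHM-5M for the growth arrest, death and stress genes CDKN1A (2.12), CITED2 (3.14), TXNIP (2.23), TP53INP1 (3.05), BMF (3.20), BCL2L11 (1.48), ATF3 (1.16), FTL (1.63), AKR1C2 (2.997), AKR1C3 (1.77), AKR1B10 (1.31), SQSTM1 (1.03), NEU1 (1.04), HIST1H2AC (1.81) and HIST1H1C (1.57). Higher among epithelial, matrix, surface and secreted genes were ELF3 (3.91), MUC1 (1.18), KRT7 (0.51), PPL (3.95), CRISPLD2 (4.79), COL9A2 (3.35), COL5A2 (1.57), FBN1 (0.87), TGFB2 (2.54), AJUBA (1.25), ITGB8 (0.80), IL7R (3.51), ACKR3 (4.33), RARRES2 (3.15), SUSD2 (2.94), PDGFRB (1.00), LIF (0.58), C3 (1.18) and KCNJ12 (1.05). Higher among lipid, thyroid, interferon and other genes were HMGCS1 (0.72), TM7SF2 (2.13), SCD (0.62), ALDOC (1.76), DIO2 (4.16), THRB (2.00), IFI27 (1.18), IFI44L (0.76), STAT2 (0.87), HLA-DMA (1.09) and ZSCAN31 (1.71). The fitted difference of EGR1 (4.37) rests on 2 counts in TTA-1 GDC-0994 and depends on the prior count.

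Of the 99 named genes called for a difference, 84 kept the call in each alternative that was run and 15 lost it in at least 1, DUSP6 and RPS6KA1 included. Without KHM-5M DMSO replicate 1, ACKR3 (adjusted p = 0.0639), MARCH4 (0.0521), CYC1 (0.0945), IFI44L (0.0539), HLA-DMA (0.0673) and PDGFRB (0.0527) were not called. Without KHM-5M DMSO replicate 2, ACKR3 (adjusted p = 0.0596), CYC1 (0.0686), IFI44L (0.0588) and PDGFRB (0.0602) were not called. Without KHM-5M DMSO replicate 3, ACKR3 (adjusted p = 0.0625), CYC1 (0.0773) and ROBO4 (0.0684) were not called. Without KHM-5M GDC-0994 replicate 1, ACKR3 (adjusted p = 0.0610) and PDGFRB (0.0651) were not called. Without KHM-5M GDC-0994 replicate 2, ACKR3 (adjusted p = 0.0652), ITGB8 (0.0530), HLA-DMA (0.0801) and ROBO4 (0.0633) were not called. Without KHM-5M GDC-0994 replicate 3, ACKR3 (adjusted p = 0.0600), CYC1 (0.112), IFI44L (0.0620) and PDGFRB (0.0501) were not called. Without TTA-1 DMSO replicate 1, ACKR3 (1.64, adjusted p = 0.863) and PDGFRB (0.58, 0.311) were not called. Without TTA-1 DMSO replicate 2, ITGB8 (adjusted p = 0.112), CYC1 (0.0560) and HLA-DMA (0.0991) were not called. Without TTA-1 DMSO replicate 3, ITGB8 (adjusted p = 0.0627), CYC1 (0.0924), IFI27 (0.0560), IFI44L (0.0606), HLA-DMA (0.110) and LAPTM5 (0.0647) were not called. Without TTA-1 GDC-0994 replicate 1, MARCH4 (adjusted p = 0.0672), CYC1 (0.0885), IFI44L (0.0598), HLA-DMA (0.0518) and PDGFRB (0.0900) were not called. Without TTA-1 GDC-0994 replicate 2, ACKR3 (adjusted p = 0.0890), MARCH4 (0.0549), PLK3 (0.0522), CYC1 (0.0980), HLA-DMA (0.0704), PDGFRB (0.0697) and ROBO4 (0.0755) were not called. Without TTA-1 GDC-0994 replicate 3, ACKR3 (adjusted p = 0.0852), HLA-DMA (0.0591) and LAPTM5 (-0.82, 0.312) were not called. With the DESeq2 Wald test, HLA-DMA (adjusted p = 0.0635) was not called. With a replicate block, IFI44L (adjusted p = 0.0545), HLA-DMA (0.0740) and PDGFRB (0.0544) were not called. With limma on log2(FPKM + 1), AKR1C2 (0.09, adjusted p = 0.439), AKR1B10 (-0.28, 0.130) and ROBO4 (-0.15, 0.365) were not called. After removal of the length and GC trend, IFI44L (adjusted p = 0.0822) and PDGFRB (0.0503) were not called. The ACKR3 difference (SE 1.56, adjusted p = 0.0481) was 6.34 without TTA-1 GDC-0994 replicate 1 and rests on means of 0.0434 CPM in TTA-1 DMSO and 0.0222 CPM in TTA-1 GDC-0994, and it depends on the prior count. Over all alternatives the adjusted p ranged from 1.72e-05 to 0.0672 for MARCH4, 1.36e-09 to 0.863 for ACKR3, 0.00391 to 0.130 for AKR1B10, 5.77e-20 to 0.439 for AKR1C2, 1.98e-06 to 0.112 for CYC1, 1.68e-05 to 0.110 for HLA-DMA, 8.50e-06 to 0.0560 for IFI27, 0.0190 to 0.0822 for IFI44L, 1.04e-05 to 0.112 for ITGB8, 2.76e-05 to 0.312 for LAPTM5, 3.11e-06 to 0.311 for PDGFRB, 0.00103 to 0.0522 for PLK3 and 0.00132 to 0.365 for ROBO4.

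GDC-0994 called 8069 genes in KHM-5M and 556 in TTA-1, or 2620 in TTA-1 without DMSO replicate 2. Deeper KHM-5M libraries as the source would bring the counts of calls together at equal library totals, but after thinning each library to 14952970 counts the ratio of calls was at least 14 in 5 thinnings of all 12 libraries. A lower spread between KHM-5M libraries as the only source would leave fold changes of equal size. The median absolute log2 fold change was 0.323 in KHM-5M and 0.119 in TTA-1 across 9528 genes. Their ratio was at least 1.73 over 36 ways of leaving out 1 library per line, which argues against spread alone. A contribution of spread was not excluded, and with each line fitted alone the calls were 8930 in KHM-5M and 206 in TTA-1. The BRAF genotype may contribute, yet with 1 line per genotype it cannot be told apart from other differences between the lines or from the medium. That difference between lines remains open as an untested biological explanation.

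MAPK output genes fell less in TTA-1 than in KHM-5M, with a median log2 difference of -2.05. A lower starting level in TTA-1 could leave less room to fall, but of the 4 members not higher in KHM-5M DMSO, 3 (DUSP4, EPHA2 and ETV5) also fell less in TTA-1, a share of 0.75, and the remaining member was EPHA4. Scaling as the source would bring the median difference near 0, and the value nearest to 0 over 4 scalings was -1.98. These scalings moved the median difference of all tested genes only between 0.021 and 0.085. They could therefore not have brought the list near 0, and they do not decide about scaling. The values show only that the list lay far from the median gene. Total RNA per cell was not measured. A difference in the lines' dependence on ERK, or in how far 1 µM GDC-0994 inhibited it in each line, was not tested and stays open.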

How the results depend on the processing

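Thinning, upper quartile scaling, library totals and the removal of the length and GC trend were chosen after the results were seen; all other settings were fixed beforehand. Of 31 settings, some were run on counts of genes alone: no low-count filter, limma on log2(FPKM + 0.1) or without a filter, a minimum fold change and thinning. The upper quartile and library total scalings were run on counts and on the medians of the MAPK output, DNA replication and mitosis lists, without a list test. No called gene, tested direction of a called list, or score reversed under the settings it was run in, except that the AKR1B10 difference between lines was -0.28 with limma on log2(FPKM + 1) (adjusted p = 0.130), and the median of the cytokines and NF-kB list in KHM-5M turned from -0.21 to 0.022 with the stricter filter. Of 3844 values of single genes 3743 kept their side of the threshold, 80 lost a call and 21 gained one. Of 1661 values of lists 1576 kept their side, 32 lost a call and 53 gained one, and of 82 counts 69 stayed within 1.5 times. The TTA-1 count of 556 was 915 with the DESeq2 Wald test, 1206 without a low-count filter, 341 with limma on log2(FPKM + 1) without a filter and 963 after removal of the length and GC trend, of which 494 were called before; the cause was not tested. With only the groups compared the TTA-1 count was 206, while the KHM-5M count rose from 8069 to 8930. Each gene's spread is then estimated within 1 line, whereas the model of all 12 libraries shares that estimate between the lines. The TTA-1 count of 556 thus rests on this sharing. Requiring a log2 fold change of at least 1 left 2598 genes in KHM-5M, 116 in TTA-1 and 1739 for the difference, by construction. The 344 calls shared between lines were 586 after removal of the trend. The score difference was -2.15 in KHM-5M and -0.67 in TTA-1 on log2(FPKM + 1), and -3.62 in KHM-5M as the median of the 10 genes, since these change what is averaged.

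Leaving out 1 library gave 7018 to 7897 calls in KHM-5M, 259 to 2620 in TTA-1, 3768 to 5186 for the difference and 11986 to 12548 in DMSO, with 185 to 1388 shared calls. For the MAPK output list the median ranged from -2.83 to -2.76 in KHM-5M, -0.93 to -0.88 in TTA-1 and -2.10 to -1.67 for the difference. After removal of the trend, leaving out 1 library gave 500 to 1651 calls in TTA-1. With a replicate block the endothelial list in TTA-1 (adjusted p = 0.0715) and the blood cell list in DMSO (adjusted p = 0.0612) were not called. Correlations across genes of library ratios for the same replicate number in DMSO and GDC-0994 were -0.00, 0.00 and -0.15 in KHM-5M and 0.27, -0.13 and -0.13 in TTA-1. Depth limits what can be said of genes near 0 counts, such as EPHA4 in KHM-5M DMSO and EGR1 in TTA-1 GDC-0994.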

Other observations

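The test for RNA from KHM-5M cells was chosen only after the result was seen. Several lists without a call as a list held genes that changed in KHM-5M, where 49.8% of all tested genes were called. Of 15 BCL2 family genes 3 rose and 6 fell (3 and 6 adjusted over the list alone; median -0.14, adjusted p = 0.560), with rises of the pro-apoptotic BCL2L11 (1.69 ± 0.11) and BMF (4.39 ± 0.16) and a fall of BCL2 (-2.03 ± 0.15). Of 8 thyroid differentiation genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; median -0.06, adjusted p = 0.167). DIO2, a deiodinase, rose from 0.153 ± 0.0676 to 2.94 ± 0.705 CPM (4.19 ± 0.29), the thyroid hormone receptor gene THRB rose (2.08 ± 0.12) and PAX8 fell from 210.2 ± 8.69 to 120.2 ± 4.08 CPM (-0.81 ± 0.09). Of 16 listed thyroid genes 8 had too few counts to be tested, among them TG, SLC5A5 and TSHR. Of 22 glycolysis genes 2 rose and 13 fell (2 and 13 adjusted over the list alone; median -0.24, adjusted p = 0.149), with ALDOC up (1.92 ± 0.16) and ENO2 down (-1.13 ± 0.08). Of 20 p53 targets 8 rose and 7 fell (8 and 7 adjusted over the list alone; median 0.25, adjusted p = 0.651).

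Metabolic and surface lists also went both ways in KHM-5M. Cholesterol synthesis had 8 of 25 up and 6 down (8 and 6 adjusted over the list alone; median -0.03, adjusted p = 0.492), with TM7SF2 (2.51 ± 0.14) and HMGCS1 (0.77 ± 0.10) up. Fatty acid synthesis had 7 of 14 up and 5 down (7 and 5 adjusted over the list alone; median 0.16, adjusted p = 0.538), with SCD up (0.66 ± 0.06). Nuclear oxidative phosphorylation had 2 of 30 up and 9 down (2 and 9 adjusted over the list alone; median -0.09, adjusted p = 0.589), with CYC1 down (-0.61 ± 0.09). Mitochondrially encoded genes had 8 of 13 up and 1 down (8 and 1 adjusted over the list alone; median 0.33, adjusted p = 0.198), the exception being MT-ATP8 (-0.93 ± 0.15). Antigen presentation had 8 of 20 up and 1, TAP2, down (-0.88 ± 0.08; 8 and 1 adjusted over the list alone; median 0.22, adjusted p = 0.149), with HLA-DMA up (1.64 ± 0.16). Receptor tyrosine kinases and ligands had 11 of 26 up and 9 down (11 and 10 adjusted over the list alone; median 0.01, adjusted p = 0.641), with PDGFRB up (1.68 ± 0.12) and MET down (-0.96 ± 0.11). YAP and TEAD targets had 11 of 22 up and 7 down (11 and 7 adjusted over the list alone; median 0.28, adjusted p = 0.282), with TGFB2 up (2.79 ± 0.11) and NT5E down from 409 ± 3.89 to 43.2 ± 3.01 CPM (-3.24 ± 0.09). For the BCL2, thyroid, cholesterol, receptor kinase, melanocytic and C cell lists the median, mean and test differed in sign in KHM-5M.

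In TTA-1, where 3.43% of all tested genes were called, few members of these lists passed. BCL2L1, which encodes BCL-xL, fell (-0.83 ± 0.13) in a BCL2 list with 1 of 15 up and 2 down (2 and 4 adjusted over the list alone; median -0.14, adjusted p = 0.248). PLK3 fell (-0.85 ± 0.15) among 20 p53 targets with 3 down and none up (4 down adjusted over the list alone; median -0.07, adjusted p = 0.0979), and IRS2 fell (-0.61 ± 0.11) among 22 arrest and quiescence genes with 1 up and 2 down (1 and 3 adjusted over the list alone; median 0.09, adjusted p = 0.997). Of 27 mesenchymal and matrix genes 1 rose and 2 fell (3 and 3 adjusted over the list alone; median 0.10, adjusted p = 0.997). KRT7 fell (-0.55 ± 0.07) among 19 epithelial genes (0 up, 2 down; 2 and 2 adjusted over the list alone; median -0.01, adjusted p = 0.997), as did PLAUR (-0.58 ± 0.09) among 25 cytokines and NF-kB targets (0 up, 2 down; 2 down adjusted over the list alone; median -0.10, adjusted p = 0.105). PDGFA fell (-0.88 ± 0.16) among 26 receptor kinases and ligands (1 up, 4 down; 1 and 5 adjusted over the list alone; median -0.03, adjusted p = 0.248). With only the TTA-1 libraries in the model IRS2 (adjusted p = 0.0655) and PDGFA (adjusted p = 0.0581) were not called. ALDH1L2, a mitochondrial folate enzyme, rose (1.06 ± 0.17) as 1 of 30 serine, one-carbon and ATF4 targets (1 adjusted over the list alone; median -0.01, adjusted p = 0.997), a call lost with limma on log2(FPKM + 1) (adjusted p = 0.0652, range 1.62e-05 to 0.0652). MT-ATP8 rose (0.91 ± 0.14) as 1 of 13 mitochondrially encoded genes (1 adjusted over the list alone; median 0.10, adjusted p = 0.126), a list that was called without GDC-0994 replicate 3 (adjusted p = 0.00306, range 0.00306 to 0.856).

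No member of 8 further lists passed in edgeR in TTA-1. At an unadjusted p under 0.05, in DESeq2, in limma on FPKM and after removal of the length and GC trend, the counts were 1, 0, 0 and 1 of 8 thyroid genes (median 0.04), 1, 1, 0 and 2 of 22 glycolysis genes (median -0.10; 1 down adjusted over the list alone), 1, 0, 0 and 0 of 30 oxidative phosphorylation genes (median -0.00), 4, 1, 0 and 2 of 25 cholesterol genes (median -0.02), 2, 0, 0 and 1 of 14 fatty acid genes (median 0.05), and 5, 0, 0 and 4 of 20 antigen presentation genes (median 0.12). They were 9, 3, 1 and 3 of 29 lysosome genes (median -0.01; 1 up and 3 down adjusted over the list alone), and 2, 1, 0 and 1 of 10 histone genes (median 0.09; 1 down adjusted over the list alone). Glycolysis was called without DMSO replicate 2 (adjusted p = 0.0426, range 0.0426 to 0.926 over all alternatives). Antigen presentation was called without DMSO replicate 1 (adjusted p = 0.0489) and after removal of the length and GC trend (0.0179), with a range of 0.0179 to 0.619. For the DNA replication, thyroid, oxidative phosphorylation, serine, lysosome, epithelial and C cell lists the median, mean and test differed in sign in TTA-1. They also differed in sign for the endothelial, melanocytic and C cell lists in the difference between lines, and for the BCL2, p53, thyroid, serine and melanocytic lists between the DMSO groups.

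Markers of other cell types gave few tested genes. Endothelial markers in TTA-1 had 1 of 6 members down, ROBO4 (-1.10 ± 0.16; 1 adjusted over the list alone), with a median of -1.52, or -0.38 without 3 members under the floor (adjusted p = 0.0404, and adjusted p = 0.184 with an estimated correlation). The call was lost without TTA-1 DMSO replicate 1 (median -0.21, adjusted p = 0.134), 2 (median -1.80, adjusted p = 0.0712) or 3 (median -0.81, adjusted p = 0.0591), or GDC-0994 replicate 1 (median -1.51, adjusted p = 0.141), over a range of 0.0106 to 0.184 for all alternatives. In KHM-5M the endothelial list had 1 up and 5 down (1 and 5 adjusted over the list alone; median -1.25, or -0.94 at the bound, adjusted p = 0.128). Of blood cell markers 2 of 3 fell there (2 adjusted over the list alone; median -1.09, adjusted p = 0.149), LAPTM5 among them (-1.09 ± 0.11). In DMSO all 3 were higher in KHM-5M than in TTA-1 (3 adjusted over the list alone; median 4.76, adjusted p = 0.00150, and adjusted p = 0.0990 with an estimated correlation), with LAPTM5 at 252 ± 5.60 CPM in KHM-5M and 0.433 ± 0.171 CPM in TTA-1. NCAM1 fell (-0.55 ± 0.11) as 1 of 3 melanocytic and neural markers (1 adjusted over the list alone; median 0.51, adjusted p = 0.926), and CALCB, at under 1 CPM, fell (-2.60 ± 0.75) as 1 of 4 C cell markers (1 adjusted over the list alone; median 0.19, adjusted p = 0.983). In TTA-1 no blood, melanocytic or C cell marker passed in edgeR, with 0 at an unadjusted p under 0.05, 0 in DESeq2, 0 in limma on FPKM and 0 after removal of the trend.

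TTA-1 DMSO replicates 1 and 2 both stood apart, and replicate 2 more so. The mean absolute log2 difference to replicate 3 was 0.217 for replicate 2 and 0.180 for replicate 1. Each log2 ratio compares a library with the other TTA-1 DMSO libraries, so opposite trends in replicates 1 and 2 are partly built in. RNA from KHM-5M cells as the source in replicate 1 would raise KHM-5M genes there. But these reached 0.309% of their KHM-5M DMSO level in replicate 1, against 0.248% to 0.322% in the other TTA-1 libraries. Gene length and GC content are a candidate explanation. Together they accounted for a share of 0.566 of the variance of this log2 ratio in replicate 1, 0.512 in replicate 2 and 0.0583 in replicate 3. GC content alone accounted for 0.552, 0.510 and 0.0451. What in the cells or the library preparation gave these trends was not tested, and no biological explanation was tested.

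Within a line, 3 libraries against 3 make 10 splits, too few for a share under 0.05. In KHM-5M the real split gave 8069 calls and the highest other 0 in edgeR. In TTA-1 it gave 556 and the highest other 391, from the split that puts DMSO replicates 1 and 3 with GDC-0994 replicate 1. Between the DMSO groups it gave 12405 and the highest other 0 in edgeR. In each of these comparisons 1 split, the real one, reached the real count. The other splits mix the groups compared and so put their difference into the spread between libraries. Counts of 0 in these splits therefore do not decide whether chance can be excluded. In TTA-1 the count of 391 was not low, although its split mixes the treatments. These calls cannot be divided between the treatment difference that the split keeps in part and other differences between libraries. The TTA-1 count of 556 may likewise hold calls that come from such other differences.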
